A study of Shewanella oneidensis MR-1 with 18 samples.

How the data were processed

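Total RNA of Shewanella oneidensis MR-1 was sequenced by the authors from lactate-fed chemostats at a dissolved oxygen tension of 20% or 8.5%, set by the ratio of nitrogen to air and sampled at steady state. Per the labels, RNA was extracted with TRIzol, treated with DNase and cleaned on columns, 16S and 23S rRNA were removed with a bacterial RiboMinus probe set except in the total RNA libraries, and strand-specific libraries were made from chemically fragmented RNA, size-selected on a gel, amplified and sequenced on SOLiD. The aligner, the counting program, the genome build and the dilution rate are not given in the sources used here. The processed files of all 18 libraries were used.

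The values tested were raw read counts per annotated feature, as deposited by the authors, 1 table per library and without normalization. Libraries of samples 1 and 4 came as feature tables with exon, coding, start and stop entries, of which only the exon entries were summed per gene, so that no read was counted again. Libraries of samples 2, 3, 5 and 6 came as gene tables, which per the file headers also give RPKM, a value scaled by the authors to gene length and counted reads. RPKM entered no test. The total it implied was compared with the summed counts of each such library, and the ratio lay between 0.9986 and 0.9991. Since the kind of table and the set (primary pair or other samples) coincide, they cannot be told apart. Of 4585 features 4419 were matched by locus tag to a RefSeq gene table, which served for names only, and 166 were not matched. Positions are those of the deposited tables.

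Libraries that share a sample number were summed, and the numbered sample was the replicate. This was settled before the data were examined, as were the tests, the gene lists, the rule for named genes and the alternatives named first below. Repeat libraries of a sample differed by more than counting noise: the median chi-square ratio over genes was 1.69 to 4.60, and 16.4% to 51.3% of genes had p under 0.05. Summed counts in tested features were 88313558, 36945126, 32092288, 97291848, 61144751 and 48379226 for samples 1 to 6. Whether numbered samples were separate cultures, and whether letters were repeat libraries of 1 culture, is not stated in the labels.

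The 28 rRNA and 103 tRNA features were left out of library sizes and tests. Counts were normalised by TMM, filtered with filterByExpr at its defaults (minimum count 10, minimum total 15) and tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from that test unless another tool is named. Standard errors were derived from the fold change and the F statistic. The common biological coefficient of variation was 0.313 for oxygen and 0.0562 for the primary pair. Comparisons were 8.5% minus 20% oxygen over 3 samples each, the libraries of sample 4 against those of sample 1, samples 5 and 6 against 2 and 3, the interaction of oxygen and set, and depleted against total RNA in samples 2 and 3. Shares of rRNA were compared by an exact permutation test.

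Lists were tested with camera in limma 3.58.1 on voom values of the 6 summed samples, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. The 28 lists covered extracellular electron transfer, anaerobic reductases, terminal oxidases, the bc1 complex, cytochrome maturation, NADH dehydrogenases, ATP synthase, hydrogenase and formate genes, lactate use, the TCA cycle, glycogen and gluconeogenesis, fatty acid synthesis and degradation, amino acid, purine and pyrimidine synthesis, nitrogen and sulfur assimilation, iron, oxidative stress, heat shock, ribosomal proteins, regulators, flagella and chemotaxis, pili and secretion, the prophages LambdaSo, MuSo1 and MuSo2, and transposases. Transposases were taken by gene symbol, since no product text was used here, and 24 of their 222 members passed the filter.

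Genes were named by a rule. It took the 10 highest and 10 lowest log2 fold changes of each oxygen comparison among genes past the threshold with a mean of at least 10 CPM and no overlap between groups. Without these conditions it added up to 4 members of each list with the smallest p, and a set of respiratory genes named in advance. For depletion the 5 highest and 5 lowest were named. Named values are means and SD of normalised CPM.

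The depleted and total RNA libraries of samples 2 and 3 are the only ones whose sample numbers pair them across a comparison, and the pairing was used as a replicate block in an alternative fit. Further alternatives were size factors by median of ratios, no filter, DESeq2 1.42.0, rRNA and tRNA kept, a threshold of 0.01, a fold change above 2, libraries as units, limma-voom with duplicateCorrelation (consensus correlation 0.925), the set as a term, counts thinned to equal totals, and leaving out each sample or library. Added after the data were seen were the small-RNA split as a term (samples 1, 4 and 5, with a tRNA share under 0.5%, against 2, 3 and 6), other small RNA features left out, and the set as a term in the list test.

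The tests were tested on simulated data with 200 changed genes. The oxygen design recovered 1.5%, 19.4% and 86.4% of changes of 1.5, 2 and 4-fold, with 7.8% false among its calls. The figures were 94%, 97% and 100% (5.8% false) for the primary pair, 9%, 52.2% and 98.5% (13.8% false) for samples 2, 3, 5 and 6, and 88.1%, 94% and 100% (4.6% false) for depletion. In this 1 simulation per design, the first 3 designs thus had a false share above the nominal 5%. In the real data these 3 comparisons called more than 200 genes, which makes the Benjamini-Hochberg cut less strict. The recovered shares may thus be lower than those of the real comparisons. For lists, 3 of 3 shifted 1.5-fold were recovered with 0 false calls by each of the 3 list tests. The simulated genes were drawn independently, so this cannot show how these tests behave when genes of a list are correlated.

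Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.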

Results

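Shewanella oneidensis MR-1, a gamma-proteobacterium that can respire oxygen, metal oxides and many other electron acceptors, was grown on lactate in a chemostat held at a dissolved oxygen tension of 20% or 8.5%, and strand-specific RNA-seq libraries were read on SOLiD instruments. The title of the series sets oxic against suboxic growth. Of the 6 numbered samples, samples 1, 2 and 3 were grown at 20% and samples 4, 5 and 6 at 8.5%. Letters were read as repeat libraries of a sample, which the labels do not state. The names of the deposited tables call samples 4, 5 and 6 anaerobic where the labels give 8.5%, and the labels were followed here. Samples 1 and 4 were taken as the primary pair that the series text names in triplicate, since only they had 3 rRNA-depleted libraries each. Samples 2, 3, 5 and 6 had 2 each, which made 14 depleted libraries. Samples 2 and 3 also had 2 libraries each from total RNA without depletion. The depleted libraries held 16648877 (library 3a) to 34877046 (4a) counts, and the 4 total RNA libraries held 4252327 (3c) to 4597213 (3d). Counts covered 4585 features, of which 4436 were genes with SO locus tags, 28 rRNA, 103 tRNA and 18 other RNA features. No count was found in any library for 207 features.

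One small RNA, csrB2, a regulator that binds the translational repressor CsrA, took 7.76% to 26.2% of all counts in a library, and the transfer-messenger RNA, which rescues stalled ribosomes, took 0.536% to 16.3%. The share of tRNA split the samples in a way that did not follow oxygen alone. It was 0.0714% in sample 1, 0.0217% in sample 4 and 0.0318% in sample 5. The other samples had more, with 3.10% in sample 2, 3.89% in sample 3 and 1.22% in sample 6. In a principal component analysis of the 6 numbered samples, the first component, with 64.9% of the variance, separated the oxygen levels. The second, with 26.6%, separated the primary pair from the other 4 samples, and the third, with 6.4%, set sample 5 farthest from sample 6.

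**Figure D1:**
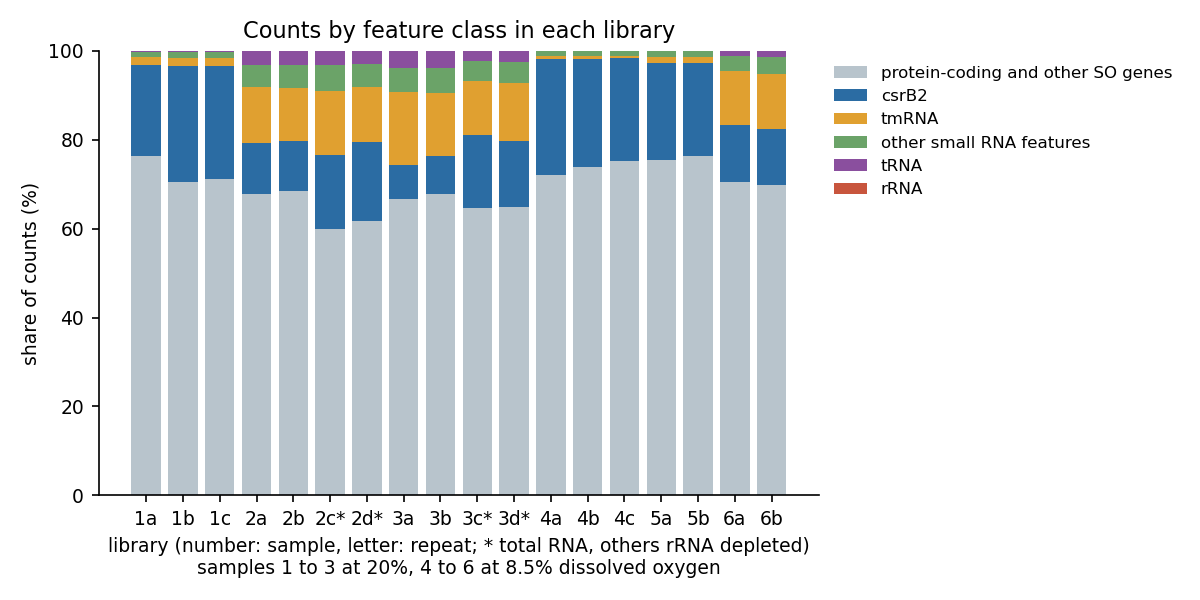
Share of all counts (percent, vertical axis) by feature class in each of the 18 libraries, with stacked bars that add to 100. csrB2 ran from 7.76% in library 3a to 26.2% in library 4a, and tRNA from 0.0199% in 4a to 3.92% in 3b.

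At 8.5% oxygen, the dimethyl sulfoxide reductase genes dmsA, dmsB, dmsE and dmsF, the pyruvate formate lyase gene pflB and the bd oxidase genes cydA and cydB rose. The haem-copper oxidase genes coxA, coxB and coxC, the TCA cycle genes acnB and mdh, the curli genes csgA and csgB and the thiamine synthesis genes thiC, thiDE and thiS fell. No gene list was called when the correlation between genes was estimated (smallest adjusted p 0.34). Over the 3 samples per level, 1477 of 4223 tested genes changed, 765 higher and 712 lower at 8.5%, and 936 of them changed more than 2-fold. The median log2 fold change (8.5% minus 20%) was 1.21 among the higher and -1.16 among the lower genes. In 1471 of the 1477 the groups did not overlap, and they did not overlap in 50.6% of all tested genes, against the 10% that chance gives for 3 against 3. All 1477 kept their sign in each alternative fit of this comparison in which they were tested. The fits of the primary pair alone and of the other 4 samples alone were not part of that check. The count fell to 787 without sample 2 and to 797 without sample 3, and rose to 2228 when the set (primary pair or the other 4 samples) was a term and to 2686 when the 14 libraries were taken as units. In the primary pair alone, where libraries of 1 sample per level were compared, it was 3442. The labels do not say that the numbered samples were separate cultures, so these p-values measure only the spread between these samples, which may be technical.

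The highest rise among the genes named by the rule fixed before the data were examined was in SO_0844, a short gene (chromosome 866486 to 866635), from 1.10 ± 0.271 to 306 ± 168 CPM (counts scaled to a common library size, mean ± SD, n = 3). Next came lrgA (SO_1047), with a log2 fold change of 7.42 ± 0.42 (SE), and lrgB (SO_1048), with 7.26 ± 0.34, which encode a holin-like protein pair. SO_4512 rose by a log2 fold change of 6.03 and SO_0403 by 5.22. The deepest fall was in the curli genes, which encode the amyloid fibre of the biofilm matrix and its export apparatus. The minor subunit csgB (SO_0866) went from 3074 ± 839 to 7.44 ± 4.58 CPM (log2 fold change -8.69 ± 0.61, adjusted p = 1.18e-04), and csgA, csgE, csgF and csgG fell by log2 fold changes of -7.68, -6.76, -6.49 and -5.60. The thiamine synthesis genes thiDE, thiC and thiS fell with values of -5.33, -5.11 and -5.09. Their neighbours in this ranking were SO_0867 (-5.41) and SO_1813 (-4.77).

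**Figure D2:**
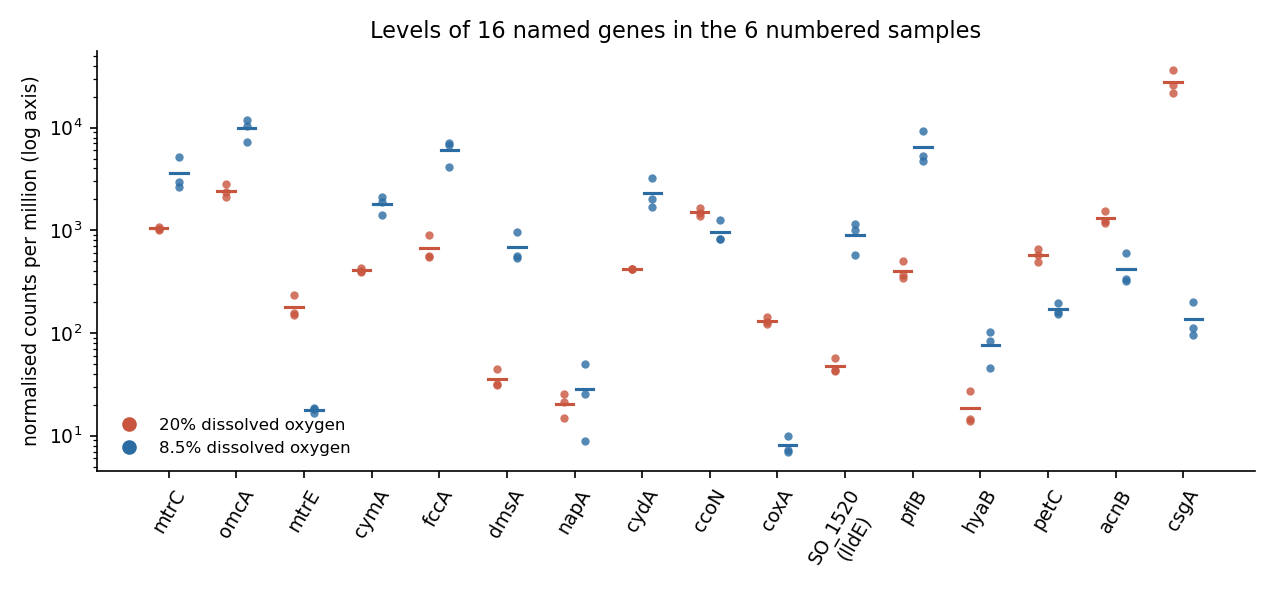
Normalised counts (CPM) on a log axis for 16 named genes, with points for the 3 numbered samples at each oxygen level and bars for their mean. In csgA all 3 samples at 8.5% lay below all 3 at 20%, in dmsA all 3 lay above, and in napA the groups overlapped.

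The genes of extracellular electron transfer to metals split by operon. Of the 9 listed, 6 rose and 3 fell, and the same counts held when adjusted over the list alone. The outer membrane conduit genes mtrC (SO_1778), mtrA (SO_1777) and mtrB (SO_1776) rose by log2 fold changes of 1.78 ± 0.31, 2.03 ± 0.33 and 1.89 ± 0.31, and the decahaem cytochrome gene omcA (SO_1779) by 2.01 ± 0.28. The inner membrane quinol oxidase gene cymA rose by 2.14 and the periplasmic fumarate reductase gene fccA by 3.16, from 673 ± 203 to 5998 ± 1584 CPM. The paralogous conduit genes next to omcA fell: mtrF by -2.91 ± 0.20, mtrE by -3.34 ± 0.23 and mtrD by -3.85 ± 0.29, with mtrD at 1.36 ± 0.342 CPM at 8.5%. The 7 mtr and omc genes lie on the minus strand between positions 1856175 and 1869219 of the chromosome in the deposited tables, whose genome build is not given in the sources used here. Because members moved both ways, the list as a whole was not past the threshold (camera adjusted p = 0.264).

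**Figure D3:**
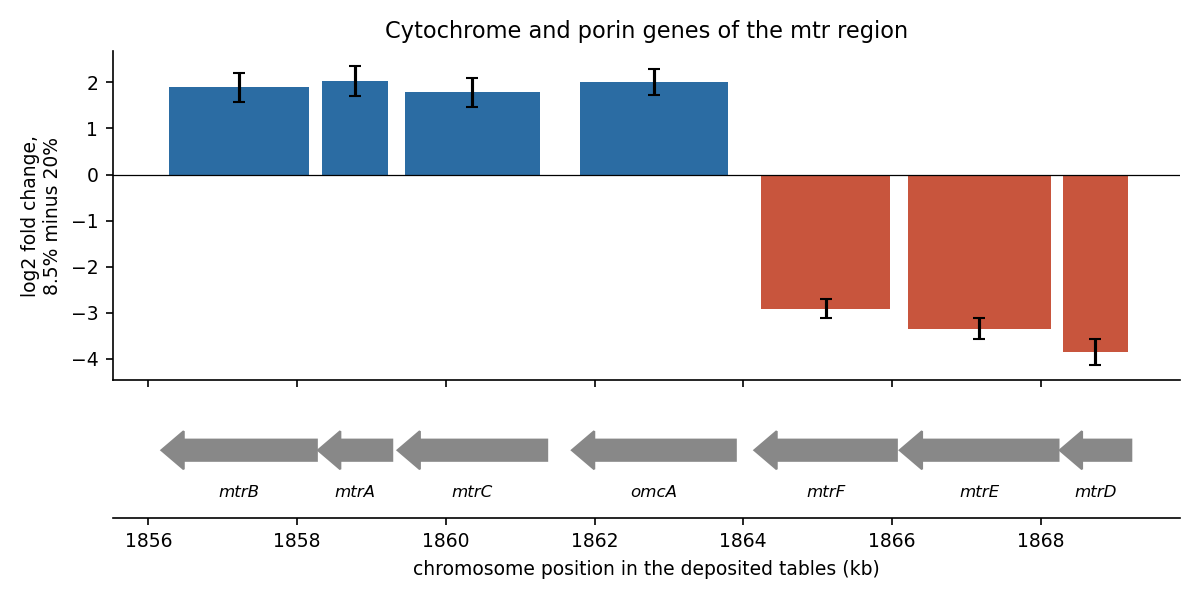
Log2 fold change (8.5% minus 20% oxygen, bars with standard error, n = 3 per level) of the 7 genes of the mtr region, over their positions in kb and their strand. mtrB, mtrA, mtrC and omcA lay between 1.78 and 2.03, and mtrF, mtrE and mtrD between -3.85 and -2.91.

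Among the reductases for other anaerobic electron acceptors, 12 of 21 genes rose and none fell. Adjusted over the list alone, 12 rose and 2 fell. The dimethyl sulfoxide reductase operon moved most, with dmsE at 5.65 ± 0.29, dmsF at 5.14 ± 0.33, dmsA at 4.25 ± 0.33 and dmsB at 4.15 ± 0.22. The nitrate reductase gene napA, at 28.3 ± 20.9 against 20.5 ± 5.40 CPM, and the nitrite reductase gene nrfA, at 136 ± 42.5 against 217 ± 10.6 CPM, were not past the threshold (adjusted p = 0.545 and 0.0667), and nrfA was past it without sample 5 (log2 fold change -0.97, adjusted p = 9.47e-03) and with the set as a term (-0.67, adjusted p = 0.0382). The list was higher as a whole (adjusted p = 2.44e-03 by camera, adjusted p = 0.34 with an estimated correlation).

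The aerobic terminal oxidases split as well, with 5 of 18 genes higher and 6 lower (6 and 7 adjusted over the list alone). The bd-type oxidase genes rose, cydA from 420 ± 1.47 to 2309 ± 834 CPM (log2 fold change 2.46 ± 0.30) and cydB by 2.35 ± 0.25. All 4 listed genes of the haem-copper oxidase operon fell, with coxC at -4.36, ctaG at -4.17, coxA at -4.03 and coxB at -3.37. The cbb3-type oxidase genes ccoO and ccoP fell by -1.02 and -0.89, and ccoN, at -0.64 ± 0.24, was not past the threshold (adjusted p = 0.0809). With a sample left out ccoO was not past the threshold without sample 1 (-0.89, adjusted p = 0.0645), sample 2 (-1.1, 0.0684) or sample 3 (-1.12, 0.0649), nor ccoP without sample 2 (-0.90, 0.0858) or sample 3 (-0.88, 0.0841), with fold changes of about the same size. ccoN was past it without sample 5 (adjusted p = 0.0161) and with the set as a term (0.0321). Of the 3 cytochrome bc1 genes petC fell by -1.77 and petB by -1.07, and petA was not past the threshold at 0.52 (1 higher and 2 lower adjusted over the list alone), but was so with the set as a term (adjusted p = 0.0326) and in the primary pair only (0.24, adjusted p = 7.47e-04). The petB call was lost without sample 1 (adjusted p = 0.0558), sample 2 (0.0583) or sample 6 (0.0557). Neither list was past the threshold as a whole, with camera adjusted p = 0.443 for the oxidases and 0.305 for the bc1 complex.

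Of 34 genes of fermentation, formate and hydrogen metabolism 20 rose and 5 fell, with the same counts adjusted over the list alone. Pyruvate formate lyase, pflB, went from 404 ± 82.8 to 6421 ± 2470 CPM (log2 fold change 3.99 ± 0.36), and the acetate kinase gene ackA rose by 3.23 ± 0.25. The formate dehydrogenase genes fdhA_2 and fdhB_2 rose by 4.66 ± 0.53 and 4.76 ± 0.46. The large subunit gene of the nickel-iron hydrogenase, hyaB, rose by 2.04 ± 0.38, whereas the accessory genes hyaE (-2.18) and hypF (-1.86), which lie downstream of it, fell. Farther downstream hypD (0.88), hypE (1.24) and hypA (1.71), looked up after the values were seen, rose. The iron-only hydrogenase gene hydA rose by 1.54 ± 0.47 at a low level of 3.93 ± 1.12 CPM, a call that was lost without sample 1 (adjusted p = 0.0579), sample 3 (0.134), sample 5 (0.127) or sample 6 (0.114). The list was higher as a whole (adjusted p = 1.07e-03 by camera, adjusted p = 0.34 with an estimated correlation).

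Of 7 lactate uptake and oxidation genes 4 rose and none fell, and 5 rose when adjusted over the list alone. The genes of the L-lactate dehydrogenase complex, SO_1518, SO_1519 and SO_1520 (lldG, lldF and lldE), rose by 4.13 ± 0.37, 4.59 ± 0.43 and 4.25 ± 0.33. The D-lactate dehydrogenase gene dldD rose by 1.11 ± 0.23, with an adjusted p of 0.0624 without sample 2 and 0.0652 without sample 3. The list was higher as a whole (adjusted p = 3.38e-03 by camera, adjusted p = 0.34 with an estimated correlation).

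Of 21 genes of the TCA cycle, glyoxylate shunt and pyruvate dehydrogenase 10 fell and none rose, and 11 fell when adjusted over the list alone. Malate synthase (aceB) fell by -1.95 ± 0.28, malate dehydrogenase (mdh) by -1.80 ± 0.18, aconitase (acnB) by -1.66 ± 0.30 and the succinate dehydrogenase subunit gene sdhB by -1.27 ± 0.18. The list was lower as a whole (adjusted p = 8.36e-04 by camera, adjusted p = 0.35 with an estimated correlation). Fatty acid degradation had 5 of 9 genes lower and 1 higher (6 and 1 adjusted over the list alone), with fadE at -1.28, fadA at -1.03 and, as the one higher member, fadR at 1.20, which encodes a regulator and not an enzyme of the pathway. That list was lower as a whole (adjusted p = 0.0402 by camera, adjusted p = 0.35 with an estimated correlation), and the call was lost without sample 1 (adjusted p = 0.0707), sample 3 (0.0514) or sample 6 (0.0576). Of the 26 NADH dehydrogenase genes 6 fell and none rose, also over the list alone, among them nqrB, nqrC, nqrD and nqrF of the sodium-pumping genes at SO_1104 to SO_1108, at -1.49, -1.50, -1.71 and -1.55. The nqrA gene directly upstream (SO_1103), looked up after the values were seen, was not past the threshold at 0.23 (adjusted p = 0.429). In the other nqr cluster, SO_0902 to SO_0907, also looked up afterwards, only nqrA fell (-0.80). The whole list was not past the threshold (camera adjusted p = 0.149).

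Of 12 ammonium assimilation genes 9 rose and none fell (10 and 1 adjusted over the list alone). Glutamine synthetase, glnA, went up by 2.85 ± 0.40, the glutamate synthase genes gltB and gltD by 1.56 ± 0.26 and 1.27 ± 0.20, and the ammonium transporter gene amtB (SO_0760) by 1.60 ± 0.19. The list was higher as a whole (adjusted p = 3.38e-03 by camera, adjusted p = 0.34 with an estimated correlation). In amino acid synthesis 17 of 50 genes rose and 6 fell (23 and 6 adjusted over the list alone), with hisG at 2.24 and metB at 1.83 against leuA at -3.06 and ilvI at -1.58, and the list was higher as a whole (adjusted p = 7.84e-03 by camera, adjusted p = 0.35 with an estimated correlation). Of 24 purine and pyrimidine genes 11 rose and 2 fell, also over the list alone, with pyrD at 1.52, purM at 1.35 and guaA at -1.19 (list adjusted p = 0.0355 by camera, adjusted p = 0.44 with an estimated correlation). Its call was lost without sample 3 (adjusted p = 0.0712), sample 5 (0.0708) or sample 6 (0.0508). In sulfate assimilation 9 of 22 genes fell and 1 rose (9 and 2 over the list alone), with cysH at -1.85, cysI at -1.65, cysN at -1.32 and cysG, which also serves sirohaem synthesis, at 1.41. The sulfate list was not past the threshold as a whole (camera adjusted p = 0.0567) but was so without sample 4 (0.0436) and with the small-RNA split as a term (0.0499).

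Of 17 genes for defence against peroxide and superoxide 7 rose and 1 fell, also over the list alone. The cytochrome c peroxidase gene ccpA went up by 3.66 ± 0.36, ahpC by 2.81 ± 0.31, ahpF by 2.28 ± 0.38 and the methionine sulfoxide reductase gene msrA by 2.62 ± 0.24, and the catalase gene katB, at 24.5 ± 8.78 against 18.6 ± 0.719 CPM, was not past the threshold. The list was higher as a whole (adjusted p = 0.0286 by camera, adjusted p = 0.34 with an estimated correlation). The iron list had 4 of 24 genes higher and 9 lower, also over the list alone. Higher were the storage genes ftn (2.87) and bfr2 (1.63) and the repressor gene fur (1.25), as was bfr1 (1.28), a further storage gene looked up after the values were seen. Lower were bfd, for a bacterioferritin-associated ferredoxin, at -2.97, and 8 genes of siderophore synthesis and iron uptake, among them the siderophore synthesis gene pubC at -1.37, also looked up after the values were seen. It was not past the threshold as a whole (camera adjusted p = 0.0557) but was so without sample 1 (0.0414), with the set as a term (0.0411) and with the small-RNA split as a term (0.0499).

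Ribosomal protein genes had 13 of 54 higher and 2 lower (13 and 1 over the list alone), with rpmI at 1.90, rpsU at 1.18 and rpsL at 0.86, the last with an adjusted p of 0.0674 without sample 2 and 0.0752 without sample 3. The list was higher as a whole (adjusted p = 0.0402 by camera, adjusted p = 0.58 with an estimated correlation), but not by fry (adjusted p = 0.185) or without sample 1 (adjusted p = 0.159), sample 5 (0.157) or sample 6 (0.0576). These genes also differed between the sets, samples 2, 3, 5 and 6 minus 1 and 4, with 25 higher and 3 lower. The median there was 0.70 (camera adjusted p = 3.91e-06 with the preset correlation), against 0.33 for oxygen. The list tests did not take gene length into account, and oxygen log2 fold changes were higher in shorter genes (median 0.24 at 300 bases or fewer). Of the 9 ATP synthase genes 3 rose and none fell, also over the list alone, with atpB at 1.22 ± 0.32, a call lost without sample 2 (adjusted p = 0.109), sample 3 (0.109) or sample 5 (0.0701). That list was higher as a whole (adjusted p = 0.0173 by camera, adjusted p = 0.35 with an estimated correlation), but not without sample 5 (0.0627). In glycogen metabolism and gluconeogenesis 6 of 14 genes rose and 1 fell, also over the list alone, with glgB at 1.94, glgX at 1.92, glgP at 1.75 and gapB at 1.26, and the list was not past the threshold (camera adjusted p = 0.0588) but was so without sample 4 (0.0436) and by fry (4.09e-03). Cytochrome c maturation had 3 of 10 genes higher, and none adjusted over the list alone (camera adjusted p = 0.0567). The maturation list was past the threshold without sample 3 (0.0344), without sample 4 (0.0436), on the 14 libraries (0.0444), with the set as a term (0.0363) and with the small-RNA split as a term (0.0314).

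The prophage LambdaSo had 35 of 70 genes lower and none higher (39 lower over the list alone), with SO_2984 at -1.80 ± 0.23 and SO_2953 at -1.16 ± 0.17. MuSo1 had 11 of 38 lower and 1 higher (10 and none over the list alone), with SO_0680 at -1.35 and the higher SO_0653, looked up after the values were seen, at 0.82, and MuSo2 had 18 of 49 lower and 1 higher (18 and 2), with SO_2680 at -1.20 and SO_2670, the higher gene, at 1.15. The last lost its call without sample 2 (adjusted p = 0.0672) or sample 3 (0.0694). The lists were lower as a whole, with camera adjusted p = 4.29e-07 for LambdaSo, 3.38e-03 for MuSo1 and 1.07e-03 for MuSo2 (each adjusted p = 0.34 with an estimated correlation). Pili and type II secretion had 10 of 49 genes lower and none higher (7 lower over the list alone), with mshD at -1.30 ± 0.24 (list adjusted p = 3.38e-03 by camera, adjusted p = 0.34 with an estimated correlation).

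The remaining lists were not past the threshold as a whole. Flagella and chemotaxis had 8 of 73 genes higher and 7 lower (5 and 7 over the list alone), with cheA (SO_2121) at -1.70, cheY_1 at -1.69 and flgF at -1.34 (camera adjusted p = 0.721). Chaperones had grpE higher at 1.67 and hslU lower at -0.67 among 20 (1 and none over the list alone, camera adjusted p = 0.35), and hslU lost its call in 5 of the 6 fits without a sample, with the highest adjusted p of 0.0842 without sample 2. Fatty acid synthesis had 1 higher, fabG_1, and 1 lower, fabZ, among 13 (none over the list alone, camera adjusted p = 0.893), and its median of -0.01 and mean of 0.16 differed in sign. The gene acpP, at 3104 ± 2638 against 721 ± 593 CPM, was not past the threshold (log2 fold change 2.11, adjusted p = 0.0665). With the set as a term acpP was past it (2.09, adjusted p = 8.36e-05), as was fabV (0.78, 8.68e-03). In that fit 4 genes of the list were higher and 3 lower. fabG_1 had an adjusted p of 0.0567 without sample 1, 0.1 without sample 2 and 0.0755 without sample 3, and of the 6 fits without a sample only the one without sample 4 kept fabZ past the threshold (highest adjusted p 0.114, without sample 6). Among 9 regulators fur and arcA rose, by 1.25 and 0.85, and the stationary-phase sigma factor gene rpoS and rpoE fell, by -2.18 and -1.27, also over the list alone, and crp and etrA were not past the threshold at 0.04 and 0.56 (camera adjusted p = 0.805). With the set as a term etrA was past it (0.56, adjusted p = 0.0256). The arcA call was lost without sample 2 (adjusted p = 0.0815) or sample 3 (0.0649), and that of rpoE likewise (0.0564 and 0.0577). The median of that list was 0.04 and its mean -0.07. No transposase gene was called among 24 tested (edgeR's quasi-likelihood test, none over the list alone, camera adjusted p = 0.792), with a median of 0.02 and a mean of -0.14, but the list was lower without sample 4 (adjusted p = 0.0436) and with the small-RNA split as a term (8.18e-03). With the set as a term 3 of these genes rose and 4 fell. The direction of the list turned to higher without samples 1, 5 or 6 (adjusted p = 0.284, 0.464 and 0.419). Transposase genes held 0.0912% to 0.103% of counts in libraries of the primary pair but at most 0.00176% in the other samples.

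Some members behind these small counts lie outside the rule for named genes and were looked up after the values were seen, and they were not followed through the alternative fits. Higher among the oxidases were also ybgT (2.04), ccoH (1.70) and cydC (0.84). Lower were the gluconeogenesis gene pckA (-1.42), the catalase-peroxidase gene katG (-0.77), guaB (-0.53) of purine synthesis, the ribosomal protein genes rpsS (-0.99) and rplB (-0.75), the hydrogenase genes hyaD (-0.97) and hyaC (-0.80), fdnG (-0.62), and fadI (-1.0) and fadH (-0.57).

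In total camera called 15 of the 28 lists, 9 higher and 6 lower, and none was called with an estimated correlation (the smallest adjusted p was 0.34, and no list had an unadjusted p under 0.05). The rotation test fry, which asks whether the genes of a list move one way and does not compare them with other genes, called 21, of which 14 were camera calls. It lost the ribosomal protein list and added the terminal oxidases, bc1 complex, NADH dehydrogenases, cytochrome maturation, glycogen, iron and sulfate lists. The other 9 splits of the 6 samples into 3 and 3 gave between 2 and 12 camera calls, so list calls with the preset correlation arose in groupings that mix the oxygen levels.

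**Figure D4:**
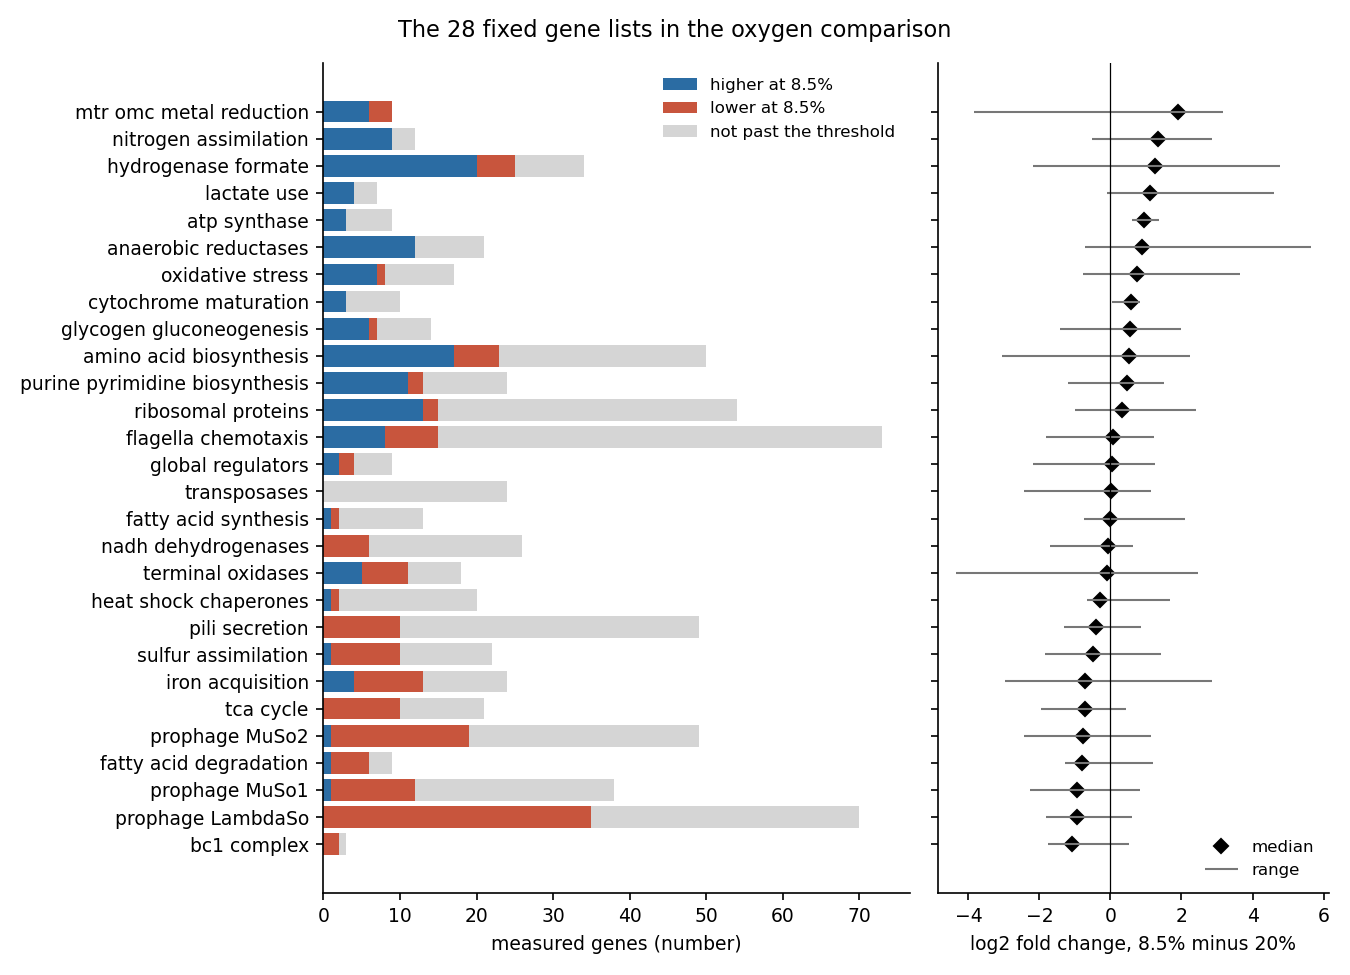
Left, number of measured genes of each of the 28 lists that were higher, lower or not past the threshold at 8.5% oxygen, and right, median and range of their log2 fold changes. LambdaSo had 35 of 70 genes lower and none higher, and hydrogenase and formate genes had 20 of 34 higher.

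Within the primary pair, sample 4 against sample 1, SO_0844 rose by a log2 fold change of 8.46 ± 0.07, lrgA by 7.85, dmsE by 5.63, ompW, for an outer membrane porin, by 4.78 and SO_1520 by 4.11, and csgB fell by -8.31 ± 0.20, csgE by -6.53, thiDE by -5.38 and the carbon starvation gene cstA by -5.12. Of 4243 tested genes 3442 changed, 1701 higher and 1741 lower, of which 981 more than 2-fold. The test compares repeat libraries of 1 sample per level and so compares these samples, not the oxygen levels. Leaving out a library gave 3294 to 3455 genes.

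In samples 5 and 6 against samples 2 and 3, which share no library with the primary pair, SO_0844 rose by 7.76 ± 0.31, lrgB by 7.19, SO_4512 by 6.06 and fdhB_2 by 5.07, and csgB fell by -9.10 ± 0.35, csgE by -7.07, thiC by -5.25 and SO_1813 by -4.74. Of 4214 tested genes 1697 changed, 886 higher and 811 lower. The count was 797 without sample 2, 760 without sample 3, 2938 without sample 5 and 3189 without sample 6, but each of these fits has 1 sample at 1 oxygen level and takes its spread from the other level alone. With the 8 libraries as units it was 2876.

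The oxygen differences of these separate sets of libraries went together across genes (Pearson r = 0.929, Spearman rho = 0.886 over 4200 genes, which are not independent replicates). Of 1637 genes called in both, 1634 changed in the same direction, 850 higher and 784 lower, where independent lists of these sizes share 357 higher and 335 lower genes. Of the genes called in the primary pair, 90.7% had the same sign in the other samples. Of the named genes called in the primary pair 2 did not, napA with -0.78 there (adjusted p = 3.75e-06) and 0.71 in the other samples (adjusted p = 0.14), and the transposase gene tnpA_ISSod8 with 0.90 (adjusted p = 0.036) and -0.94 (adjusted p = 0.0859). A test of the difference itself, the interaction of oxygen and set, called 0 of 4263 genes by edgeR's quasi-likelihood test, with 92 at an unadjusted p under 0.05, 0 with size factors by median of ratios (94 unadjusted) and 718 when the 14 libraries were taken as units. On simulated counts of this design, 37.9% of genes with a 4-fold difference in effect and 1.5% of those with a 2-fold difference were recovered.

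**Figure D5:**
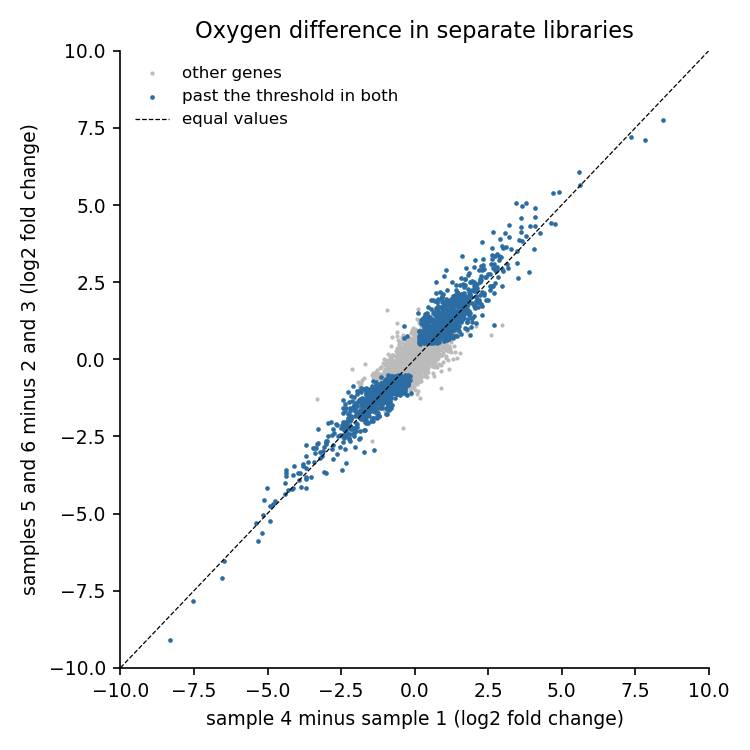
Log2 fold change at 8.5% against 20% oxygen per gene in sample 4 against sample 1 (horizontal axis) and in samples 5 and 6 against samples 2 and 3 (vertical axis), with the line of equal values. Across 4200 genes Pearson r was 0.929, and 1634 of the 1637 genes past the threshold in both (blue) lay on the same side of 0.

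Depletion of rRNA was compared with total RNA in samples 2 and 3 at 20% oxygen. Most called genes were lower after depletion. SO_2061 fell from 33.7 ± 0.844 to 6.46 ± 1.06 CPM (SD, n = 2; log2 fold change -2.39 ± 0.14), SO_1612 by -1.50, SO_0335 by -1.37, ygfZ, a folate-binding protein gene of iron-sulfur cluster repair, by -1.36 and SO_4823 by -1.31. The highest rises were in SO_0447 (0.62), SO_3086 (0.60), the leader peptide gene ilvL (0.56), SO_A0057 (0.51) and SO_2585 (0.48). Of 4184 tested genes 196 changed, 20 higher and 176 lower, and 18 changed more than 2-fold. With the numbered sample as a replicate block the count was 127, 5 higher and 122 lower, all of them among the 196, and the call of SO_A0057 was lost (adjusted p = 0.0865). With the 8 libraries as units and the same block it was 486, 171 higher and 315 lower.

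Counted rRNA was scarce in either preparation. It made up 0.0158% ± 7.76e-04 of counts in total RNA and 2.44e-04% ± 4.50e-05 after depletion (SD, n = 2 numbered samples each), a ratio of 64.7. These are shares of counted reads, and the counting program is not given in the sources used here. Whether rRNA reads were left out before or during counting is thus not known. The ratio therefore does not measure how much rRNA the depletion removed. The two-sided exact permutation p was 0.333, the smallest that 2 against 2 can give. Sample 1, which was depleted, had 0.133% to 0.164% rRNA counts per library and sample 4 had 0.0225% to 0.0306%, both above the total RNA libraries at 0.0143% to 0.0184%, and the tables of the primary pair had another layout than those of the other samples.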

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

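Of the tests weighed below, those of short genes, of depth and of other splits were written before the data were seen, and all others after the pattern had been seen. Among 21 groups of libraries checked, 2 values lay far from the rest of their group, where chance alone marks about 1 group in 20. Library 1a had 23.46% of its counts in other RNA features, the lowest of the 7 depleted libraries at 20% oxygen, where the other 6 had 28.4% to 29.5%. Total RNA library 2d had 18.19% of gene counts in its 10 most counted genes, among only 4 total RNA libraries compared.

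Depleted libraries of samples 1, 4 and 5 had smaller shares of tRNA and transfer-messenger RNA than those of samples 2, 3 and 6, whereas csrB2 went the other way, at 20.5% to 26.2% against 7.76% to 13.0%. The oxygen level alone does not account for it, since the highest tRNA share at 8.5% oxygen was 17.0 times the lowest at 20%. The kind of table alone does not either, since sample 5, a gene table sample, had 0.03175% tRNA. Within each set, however, tRNA shares were lower at 8.5% oxygen. Sample 4 had 0.0217% against 0.0714% in sample 1. Samples 5 and 6 had 0.03175% and 1.22% against 3.10% and 3.89% in samples 2 and 3. A part played by oxygen beside the set was not tested. A loss of short RNA during preparation could not be told from its absence: between samples 6 and 5, genes of at most 300 bases (236) and over 1000 bases (1445) differed in median log2 difference by -0.02 (95% interval -0.14 to 0.06). With the split as a term, the oxygen count was 1681, and whether it came from the cultures or the libraries stays open.

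Transposase genes were low in samples 2, 3, 5 and 6. Oxygen does not account for it, since within a kind of table the log2 ratio of their shares, 8.5% minus 20%, was -0.46 in gene tables and 0.14 in feature tables. Whether a loss of reads shared by near-identical copies accounts for it cannot be told. The median log2 difference was -6.46 for 22 genes of families with 1 named copy and -7.56 for 37 genes of families with several. Families were told apart by gene symbol and not by sequence, so genes with 1 named copy may still share reads with others. The duplicated genes tufA and tufB had -0.22 and -0.49, so a loss of that size did not strike all duplicated genes. The lowest share in a feature table was 51.9 times the highest in a gene table, a gap that a counting rule of the gene tables might give. It cannot be told apart from a difference between the sets, which coincide with the kind of table.

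Genes called after rRNA depletion were mostly lower. Depth does not account for it, since with depleted libraries thinned to the totals of the total RNA libraries 89.1% of 174 calls (155) were lower. Nearness to rRNA does not either, as 2.8% of the lower genes (5 of 176) lay within 5 kb of an rRNA feature against 1.7% of other genes. If such a loss had struck samples 2, 3, 5 and 6 but not the primary pair, the 176 genes should be lower in samples 5 and 6 than in sample 4: their median log2 difference was -0.13, with 58% lower against 48.3% of all genes (permutation p over 10000 randomly drawn gene lists = 2e-04, with genes not independent). This cannot tell, and off-target removal stays open.

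The real split of the samples gave 1477 genes, and the highest of the 9 others gave 1 (samples 1, 4 and 5 together). For the libraries of the primary pair the values were 3442 and 0, and for lists 15 and 12 (samples 1, 5 and 6 together). In each case 1 of 10 splits reached the real value, and with 10 splits the share cannot be under 0.05. Every other split also mixes the oxygen levels within its groups, so a difference between the levels adds to its spread. Low gene counts in those splits are thus no evidence about chance.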

How the results depend on the processing

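The alternatives were planned before the data were seen, except the small-RNA split as a term, the fit without other small RNA features and the set as a term for lists, which were added after. Where no cause is named below, the cause was not tested.

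The oxygen count of 1477 (765 higher, 712 lower) stayed within 1.5-fold, at 1437 to 1754, with other size factors, no filter, DESeq2, rRNA and tRNA kept, duplicateCorrelation, thinning and both added fits. It was 2686 (1373 and 1313) with 14 libraries as units, which adds replicates that were read as repeats of a sample. It was 2228 (1163 and 1065) with the set as a term, 742 (369 and 373) at a threshold of 0.01, 936 (489 and 447) with a fold change above 2, 3442 (1701 and 1741) in the primary pair only and 1697 in the other samples only. Leaving out a sample gave 787 (without sample 2) to 1486 (without 4), with 365 to 771 higher and 421 to 715 lower. The values without sample 3 were 797, 376 and 421, and without sample 2 422 were lower. Fewer samples were tested in these fits.

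The primary pair count of 3442 stayed at 3110 to 3465. The count of 1697 for samples 2, 3, 5 and 6 was 2876 with 8 libraries as units and 720 at a threshold of 0.01, and without a sample it ran from 760 (without 3) over 797 (without 2) and 2938 (without 5) to 3189 (without 6), in fits where 1 oxygen level has 1 sample and the spread comes from the other alone. The interaction count was 0, 0 with other size factors and 718 with 14 libraries as units. The correlation of 0.929 was 0.937 among genes with at least 10 CPM.

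The depletion count of 196 was 164 to 208 with other size factors, filter, test and features, 127 with the replicate block, 486 with 8 libraries and the block and 111 at a threshold of 0.01. Leaving out a sample was not run for depletion, as no residual degrees of freedom remain. Over all non-coding features the share was also higher in total RNA, by 4.91 percentage points against 0.0156 for rRNA alone. Since rRNA was only 0.0158% of counts within a non-coding share of 37.25%, the larger difference does not bear on rRNA.

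The 15 list calls were 0 with an estimated correlation, 21 by fry, 16 with 14 libraries, 17 with the set as a term, 19 with the small-RNA split as a term and 12 to 19 without a sample.

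Of 149 named genes, 124 (without sample 3) to 148 kept direction and side of the threshold in each alternative fit. The sign changed for 5 of them, none past the threshold in the oxygen test. crp (0.04) was -0.04, -0.03 and -0.01 without samples 2, 4 and 5, -0.05 with the small-RNA split as a term, and reached 0.12 without sample 6. napA (0.47) was -0.25 without sample 5 and -0.78 in the primary pair only, with 0.90 without sample 4 as its highest. The transposase genes tnpA_MuSo1a (-2.27) and tnpA_MuSo2b (-2.44) ran from -7.92 and -5.87 without sample 4 to 1.65 and 1.19 without sample 1. tnpA_ISSod8 (-0.73) was 0.34 with the small-RNA split as a term and 0.90 in the primary pair only. At this depth and number of samples, 2-fold oxygen changes were recovered in 19.4% of simulated genes. The simulation changed 200 genes, fewer than the 1477 called here, which makes the Benjamini-Hochberg cut stricter. The recovered share may thus be too low for the real comparison. A gene not past the threshold may still have changed by this much.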

Other observations

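These gene groups and the 1 test below were chosen after the values were seen, and 21 groups, 2 of them replicons, were looked at. All 6 curli genes were lower at 8.5% oxygen, including the regulator gene csgD at -1.88 (79.6 ± 10.7 against 294 ± 36.0 CPM, SD, n = 3). Of 8 thiamine genes, 6 adjacent ones were lower, from thiH at -4.13 to thiDE at -5.33, whereas thiI, which also serves tRNA modification, was higher at 0.99 and thiL was not past the threshold (0.37, adjusted p = 0.11 by edgeR). Of 12 cobalamin genes 7 were lower, with cobT at -1.56 and btuB at -1.02. Of 12 formate dehydrogenase genes 9 were higher, with fdhF at 3.98. None of 13 nuo genes passed the threshold (edgeR), with values from -0.47 to 0.63, whereas 6 of 13 nqr genes were lower and 1, nqrM, was higher (0.89). The small RNA csrC was lower at -1.22 (1457 ± 130 against 3399 ± 882 CPM), and csrB1 and csrB2 were not past the threshold at 1.34 and 0.54, in features whose counts also follow the small-RNA split. On the megaplasmid 34 genes were higher and 14 lower of 124.

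Oxygen log2 fold changes fell with coding length (Spearman rho = -0.19). The median was 0.24 for 391 genes of at most 300 bases, 0.12 for 2248 genes of intermediate length and -0.17 for 1566 genes over 1000 bases. With the small-RNA split as a term the medians were 0.29, 0.10 and -0.17.

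In the hya and mtr regions neighbouring genes of 1 strand moved in opposite directions. Going downstream, values fell from hyaA (1.52) and hyaB (2.04) to hyaE (-2.18), then rose from hypF (-1.86) to hypA (1.71), and in the mtr region they rose from mtrD (-3.85) to mtrB (1.89). The hypothesis that transcripts at 8.5% oxygen fall along runs of genes was put to 968 neighbouring pairs. The median of downstream minus upstream log2 fold change was -0.016 (95% interval -0.056 to 0.027, with pairs taken as independent), and 51.1% of pairs were lower downstream. For these pairs the values argue against a general fall with a median below -0.056. A smaller fall along runs cannot be told from none.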
